A study of Sesamum indicum with 6 samples.

How the data were processed

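Bulk segregant RNA sequencing was carried out on young leaves of 17-day-old sesame (Sesamum indicum) seedlings grown at 28 °C by day and 22 °C by night with 12 h of light. The plants came from recombinant inbred lines, each a near-homozygous mosaic of its parents. They were homozygous for either of 2 alleles on linkage group 8, SiCD-A, which carries wild-type KAN1, or SiCD-B, which carries the mutant kan1. Each allele group held 19 plants, and RNA of 9 plants drawn at random was mixed in equal amounts to make each of 3 pools per group, per the labels. The 27 places in the pools of a group exceed its 19 plants by 8, so pools of a group must share plants. The p-values therefore measure the spread between overlapping pools of the same plants and leave out chance differences between the 2 sets of 19 plants at other loci.

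Libraries were made with a TruSeq version 2 kit, which does not mark strand, and read as pairs of 100 bases. The submitters' processing notes name FastQC 0.11.4, Trim Galore, STAR, SAMtools, HTSeq and DESeq2. The genome build and the versions of the other tools are not given in the sources used here. The deposited counts are whole reads per gene for 25762 genes and 6 pools, with no normalization. The deposited normalized signal of 21816 genes equals the counts divided by a single factor per pool, tested on the file, and every gene in it has at least 20 counts over the pools. The authors' deposited table of log2 fold changes and adjusted p-values covers 20661 genes and gives a product name and the position of a coding segment for each. A shorter deposited table lists 100 genes with log2 fold changes, p-values and linkage groups.

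All 25762 gene identifiers occur in the RefSeq table of assembly S_indicum_v1.0, which was used for linkage group names, gene types and neighbours. Coordinates are those of the coding segment in the deposited table, whose build is not named. The linkage group assigned to each sequence matched the authors' for 97 of the 97 genes they placed on a linkage group.

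The counts were tested with edgeR 4.0.16 in R 4.3.3, by the quasi-likelihood test with robust fitting, TMM scaling and the filterByExpr filter. The contrast was SiCD_B minus SiCD_A over all 6 pools, without covariates. Every adjusted p given for a gene is the Benjamini-Hochberg value of this test over 21009 genes, and a gene was called below 0.05. The standard error of a log2 fold change was its size divided by the square root of the test statistic F. CPM are counts scaled to a library of 1000000 with TMM factors.

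Before the data were examined, 19 gene lists were fixed by words in the product names, covering leaf polarity, hormones, cell wall, photosynthesis, cell division, ribosomes, defence, heat shock, secondary metabolism, the clock and 4 sets of markers of other tissues. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the 19 lists. Camera with an estimated correlation and fry were run beside it. Another 9 lists were chosen after the data had been seen. The rule for the genes named was also fixed beforehand. It took the KANADI genes, then the 10 largest changes in each direction among called genes with a product name, a mean CPM of at least 1 and no overlap between groups. It added up to 4 members of each list by smallest p and up to 2 genes without a product name in each direction. Where a gene outside it is named, the text says so.

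Called genes on each linkage group, and in windows of 1 Mb, were compared with the rest by two-sided Fisher's exact tests. The background was every tested gene with a linkage group. Alternatives were DESeq2 size factors, upper-quartile factors, library size alone, no filter, a CPM of at least 1 in 3 pools, the DESeq2 1.42.0 Wald test, limma-voom, the pool number as a block, a limit of 2-fold, windows of 2 Mb, and leaving out each pool in turn.

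The fit was tested on simulated data for this contrast, drawn for the 21009 tested genes, of which 20914 passed the filter again. It recovered 71.4% of genes changed 1.5-fold, 85.7% of those changed 2-fold, 92% at 4-fold and 98% at 8-fold. Of 214 simulated calls, 26 were unchanged genes, which is above the nominal share. Only 200 genes and a shifted list were changed, and the pools were drawn independently. These shares therefore need not hold for the real pools, which share plants and differ in far more genes. Total counts were 56123250 to 82165322 per pool, so that 3 counts, the limit set by a count of 0, correspond to 0.0365 to 0.0535 CPM before scaling. Such limits cover counting error only. Pools of a group differed beyond sampling noise (chi-square per degree of freedom 5.24 to 29.7), so no library was counted as a repeat of another. Figures were drawn with matplotlib 3.10.9.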

Results

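RNA abundance in young leaves was compared between sesame seedlings homozygous for the SiCD-A allele and seedlings homozygous for the SiCD-B allele of linkage group 8. SiCD_A carries wild-type KAN1 and SiCD_B the mutant kan1, and each group was represented by 3 pools of RNA. The SiCD_A pools held 73127507, 74705569 and 56123250 counts, and the SiCD_B pools held 77087956, 82165322 and 74331695. Of 25762 genes, 23751 had at least 1 count and 21009 were tested. The first principal component separated the groups and held 60.0% of the variance. The next, with 14.9%, set SiCD_A pool 3, the shallowest, apart from the other SiCD_A pools.

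The transcript of KAN1 itself was examined first. KANADI proteins are transcription factors that specify the lower (abaxial) side of leaves. KAN1 (LOC105167765, linkage group 8, coding segment 5061716 to 5062586) was 2.40-fold higher in the mutant-allele pools. Its level was 22.7 ± 2.30 CPM in SiCD_A and 54.4 ± 1.88 CPM in SiCD_B (SD, n = 3 pools each). KAN1-like (LOC105178203, linkage group 15, 7864042 to 7864891) was nearly silent in SiCD_A, with 2, 11 and 6 counts, against 195, 172 and 182 counts in SiCD_B. The KAN2 gene LOC105156014 on linkage group 2 rose from 21.7 ± 3.54 to 34.6 ± 3.13 CPM (SD, n = 3).

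In edgeR's quasi-likelihood test the log2 fold change of KAN1 was 1.26 (SE 0.07, adjusted p = 3.33e-05), and that of KAN1-like was 4.59 (SE 0.36, adjusted p = 0.000130). KAN2 LOC105156014 changed by 0.68 (SE 0.12, adjusted p = 0.00543). The other KAN2 gene, LOC105155509, had a log2 fold change of 0.08 (SE 0.10, adjusted p = 0.613) and did not pass. KAN4 (LOC105166208), near 1 CPM, changed by 1.06 (adjusted p = 0.0145). Its call was lost without SiCD_A pool 1 (adjusted p = 0.0541) or SiCD_B pool 2 (0.0648). The labels give no sequence for kan1, so a transcript level neither supports nor contradicts them, and counts cannot separate reads of KAN1 and KAN1-like where their sequences are shared.

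**Figure D1:**
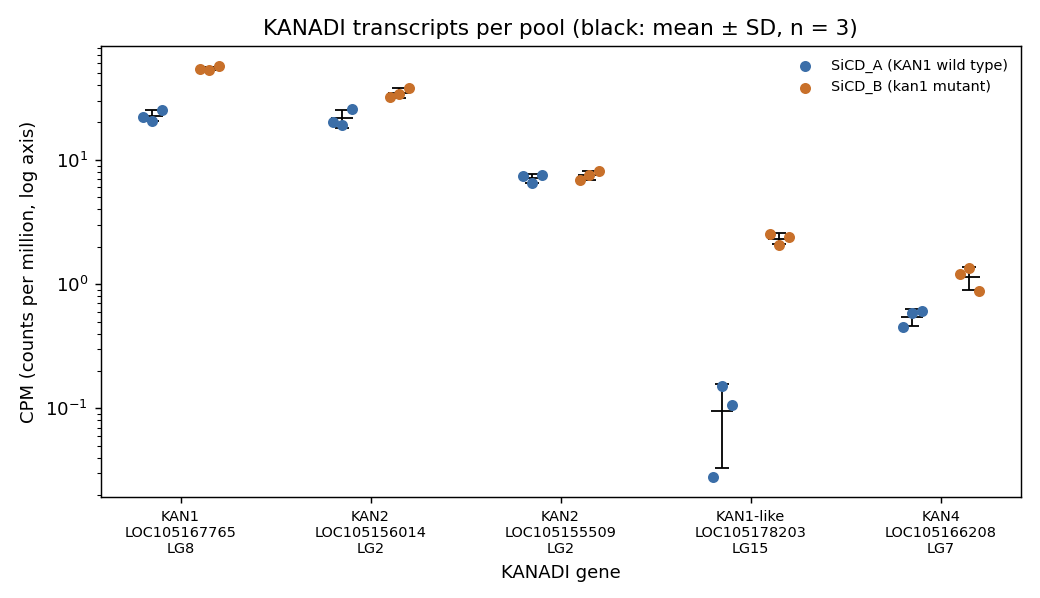
CPM of the 5 KANADI genes on a log axis, 1 point per pool, with black bars for the mean ± SD of 3 pools. The pools of KAN1 average 22.7 CPM in SiCD_A and 54.4 CPM in SiCD_B, and those of the KAN2 gene LOC105155509 overlap.

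Across all genes, 6433 of 21009 (30.6%) differed between the groups in edgeR's test, 3462 higher and 2971 lower in SiCD_B. Most shifts were small, and 264 genes rose and 352 fell at least 2-fold. Pools of the 2 groups did not overlap for 10173 genes (48.4%), against 10% expected by chance for 3 against 3 independent pools, which pools sharing plants are not. Among the largest increases were asparagine synthetase (LOC105163945), which makes the amide used for nitrogen transport, and TM9SF2 (LOC105167774), a membrane protein gene on linkage group 8. Asparagine synthetase went from 0.174 ± 0.0730 to 3.05 ± 1.73 CPM, a log2 fold change of 4.11 (SE 0.57). TM9SF2 went from 1.39 ± 0.0165 to 15.8 ± 0.682 CPM, a log2 fold change of 3.51 (SE 0.09, adjusted p = 1.57e-07).

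A JAGGED-like zinc finger gene (LOC105160902), of a family that promotes blade growth, was also among the 10 largest increases, with a log2 fold change of 2.47 (SE 0.31). MYB28-like (LOC105160076) had 2.23 and the homeobox gene BEL1-like 9 (LOC105161586) 2.08. Myb-like Q (LOC105160073) had 2.98, the transporter-like WAT1 (LOC105179601) 2.21 and 3-hydroxyisobutyryl-CoA hydrolase 3 (LOC105172216) 2.21. Sulfate transporter 1.3 (LOC105158922) had 3.49 with an adjusted p of 0.0440. Its call was lost without every pool except SiCD_B pool 3 (adjusted p = 0.0873 to 0.126), with limma-voom (0.0982), with no filter (0.0625) and with pool number as a block (0.160).

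The largest decrease with a product name was in a SENESCENCE-ASSOCIATED GENE 21-like gene (LOC105163113), from 2.17 ± 0.700 to 0.0698 ± 0.0550 CPM, a log2 fold change of -4.89 (SE 0.45, adjusted p = 0.000227). The ribosomal protein gene RPL19-3-like (LOC105166465) had -4.84 and an acetylajmalan esterase gene (LOC105158729) -4.82. Cytochrome P450 genes of the CYP72A219 type fell by 4.12 (LOC105165829) and 3.70 (LOC105165601) on the log2 scale. Aluminum-activated malate transporter 4 (LOC105161200), an anion channel, had -3.93, and a GRV2-like DnaJ gene (LOC105179447) -3.40. Ubiquinol oxidase 2 (LOC105172762), the alternative oxidase of mitochondria, had -3.18 and RADIALIS-like (LOC105169642) -2.93. Geraniol synthase (LOC105163844), which makes a monoterpene alcohol, had -3.64 (adjusted p = 0.0216), but its call was lost without SiCD_A pool 1 (0.0619), SiCD_A pool 2 (0.0557) or SiCD_B pool 1 (0.0699), and with the block (0.0940).

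Of genes without an informative product name, 2 in each direction were named. LOC105167770, a long non-coding RNA that the RefSeq table of S_indicum_v1.0 places on linkage group 8 between LOC105167769 and LOC105167771, rose from 1.43 ± 0.205 to 30.6 ± 0.914 CPM (SD, n = 3). LOC105175972 on linkage group 13 rose less, from 7.92 ± 1.43 to 24.6 ± 8.17 CPM, a log2 fold change of 1.63 (SE 0.30, adjusted p = 0.0127), and its call was lost without SiCD_A pool 3 (adjusted p = 0.0637). LOC105179424, also a long non-coding RNA, had 417 counts in SiCD_A and 0 in SiCD_B. It was at least 165-fold lower, with the floor set at 3 counts over the group. LOC105179708 fell from 12.9 ± 0.588 to 0.155 ± 0.0326 CPM.

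With library size as the only scaling, 4515 genes were higher and 2169 lower, a share of 67.5% higher against 53.8% in the main fit. With DESeq2 size factors 3223 were higher and 3183 lower (50.3% higher), and with upper-quartile factors 3131 and 3297 (48.7%). The balance of higher and lower genes thus hangs on the scaling. Leaving out SiCD_B pool 2 lowered the number of calls from 6433 to 3919, of which 3871 were among the 6433. In the authors' deposited table, 6553 of 20661 genes had an adjusted p under 0.05, 3227 higher and 3326 lower.

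The gene lists ask which functions moved with the allele. Of 25 tested leaf polarity genes, 20 were higher and 0 lower, with a median log2 fold change of 0.46 (camera adjusted p = 7.37e-09 at the preset correlation between genes, 0.0967 with an estimated correlation). They included KAN1 itself, the member of smallest p, and genes of both leaf faces. YABBY 1-like (LOC105173319) and auxin response factor 4 (LOC105170702), both named for genes that act on the lower side, rose by 0.95 (SE 0.06) and 0.75 (SE 0.06). REVOLUTA (LOC105170294), a homeobox gene of the upper side, rose by 0.80 (SE 0.06). Cell cycle genes were higher for 79 and lower for 1 of 104 members, with a median of 0.54 (camera adjusted p = 2.40e-19, or 0.240 with an estimated correlation). Histone H3.2 (LOC105172647), which packages new DNA, rose by 0.86 and mitotic cyclin-2 (LOC105158888), which drives entry into mitosis, by 0.68.

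Auxin genes, of the hormone that directs organ outgrowth, were higher for 53 and lower for 8 of 134 members (median 0.29, camera adjusted p = 4.89e-06, or 0.0967 with an estimated correlation), and the lower ones numbered 5 without SiCD_B pool 2. The repressor IAA9-like (LOC105158554) rose by 0.88 and the efflux carrier PIN7-like (LOC105160071) by 0.82, while auxin-binding protein ABP19a (LOC105157802) fell by 0.99. Meristem and organ boundary genes were higher for 14 and lower for 1 of 40 members (median 0.43, camera adjusted p = 0.00175, or 0.0967 with an estimated correlation). WUSCHEL-related homeobox 1 (LOC105166551), known for lateral growth of the blade, rose by 1.60 (SE 0.08), from 4.54 ± 0.307 to 13.8 ± 0.204 CPM. LOB domain gene 25-like (LOC105176418) rose by 3.21 from a level near 0.1 CPM.

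Heat shock genes, which encode chaperones, were lower for 34 and higher for 5 of 77 members (median -0.28, camera adjusted p = 6.61e-07, or 0.0967 with an estimated correlation). Without SiCD_B pool 2, 3 were higher. Heat shock cognate 80-like (LOC105176572) fell by 0.50 and the small class I protein 16.9 kDa 2-like (LOC105161577) by 1.52. Clock genes were lower for 9 and higher for 0 of 23 members (median -0.17, camera adjusted p = 0.00175, or 0.240 with an estimated correlation), including the dawn gene LHY-like (LOC105173131), at -1.09 (SE 0.13), and GIGANTEA-like (LOC105158892), at -0.37 (SE 0.07). Without SiCD_A pool 1, SiCD_B pool 2 or SiCD_B pool 3, the lower clock genes numbered 4, 5 and 5. Vascular markers were lower for 9 and higher for 2 of 16 (camera adjusted p = 0.00511, or 0.264 with an estimated correlation), and 5 were lower without each of these same pools. Among the vascular markers, SIEVE ELEMENT OCCLUSION B genes, which encode phloem filament proteins, fell by 0.54 (LOC105176450) and 0.33 (LOC105176465).

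Cytosolic ribosome genes were higher for 50 and lower for 6 of 216 members, with a median of only 0.06 (camera adjusted p = 0.00175, or 0.882 with an estimated correlation). L37a (LOC105167587) rose by 0.35, while L19-3-like went the other way. Of these, 16 were higher without SiCD_B pool 2, 22 without SiCD_A pool 1 and 33 without SiCD_A pool 3, and 82 with library size alone. Photosynthesis genes were lower for 9 and higher for 4 of 63 (median -0.13, camera adjusted p = 0.0419, or 0.882 with an estimated correlation). Without SiCD_A pool 3, which also stood apart on the principal components, 41 were lower and 4 higher, while 2 were lower without SiCD_A pool 1 or 2 and 1 without SiCD_B pool 2 or 3.

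With camera at the preset correlation, 9 of the 19 lists passed. With an estimated correlation 0 of the 19 lists passed and 4 had an unadjusted p under 0.05. That form of camera also has fewer degrees of freedom, so the loss is not due to correlation between genes alone. The meristem and boundary list had an estimated correlation of -0.0058, below the preset 0.01, yet its camera adjusted p went from 0.00175 to 0.0967. Fry, which tests whether members move on balance to one side, also gave 9 lists, but not the same ones. Its adjusted p was 0.00066 for leaf polarity and 0.0026 for cell cycle, it added the cytokinin (0.0157) and lignan (0.0494) lists, and it left out cytosolic ribosome (0.247) and photosynthesis (0.562). Camera at the preset correlation also called 3 to 8 lists in the 9 other splits of the pools, where edgeR called 0 genes and fry 0 lists. Each of these splits set 2 pools of a group together with 1 of the other. Part of the difference between groups thus remained and the rest entered the spread. These counts therefore do not show what each test gives without a difference. The camera call of photosynthesis was lost without SiCD_A pool 1, SiCD_A pool 2, SiCD_B pool 2 or SiCD_B pool 3 (adjusted p = 0.396, 0.302, 0.126 and 0.170), with DESeq2 size factors (0.0545) and with upper-quartile factors (0.0561). That of cytosolic ribosome was lost without SiCD_B pool 2 (0.126).

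Adjusted over the list alone, 20 leaf polarity genes were higher and 0 lower, 83 and 3 for cell cycle, 57 and 13 for auxin, and 14 and 1 for meristem and boundary. The numbers were 6 higher and 37 lower for heat shock, 0 and 9 for the clock, 2 and 10 for vascular markers, 44 and 5 for cytosolic ribosome, and 4 and 8 for photosynthesis.

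The other 10 lists did not pass camera. Cytokinin, gibberellin and brassinosteroid genes were higher for 11 and lower for 4 of 53 (adjusted over the list alone 11 and 4). Jasmonate and ethylene genes were higher for 25 and lower for 22 of 166 (25 and 22). Its members of smallest p were AP2-type growth regulators named for an ethylene-responsive domain, such as ANT (LOC105159085), which promotes organ growth and rose by 1.76 (SE 0.12). Fruit dehiscence genes were higher for 5 and lower for 3 of 12 (5 and 4), mostly BEL1-like homeobox genes. Lignin genes were higher for 7 and lower for 11 of 78 (7 and 10), and cell wall loosening genes for 26 and 17 of 142 (26 and 17). Defence genes were higher for 12 and lower for 20 of 163 (11 and 16), flavonoid genes for 9 and 8 of 50 (9 and 8), and lignan genes for 3 and 1 of 19 (3 and 0). Flower genes were higher for 6 and lower for 2 of 32 (6 and 2), and trichome and epidermis genes for 23 and 7 of 115 (23 and 7). The trichome list includes trichome birefringence-like genes, which the name alone does not make markers of trichomes. EPIDERMAL PATTERNING FACTOR-like 2 (LOC105159073), of a family of signal peptides, rose by 1.36. Several of these numbers hung on single pools. Without SiCD_B pool 2, lower lignin genes numbered 4, cell wall genes 14 higher and 9 lower, lower defence genes 11 (13 with library size alone), flavonoid genes 4 and 2, higher cytokinin genes 7, and trichome and epidermis genes 15 and 4. Without SiCD_B pool 3, higher jasmonate genes numbered 16, higher cytokinin genes 7, higher lignin genes 4, higher cell wall genes 17, and flavonoid genes 5 and 5. Without SiCD_A pool 1, lower lignin, flavonoid and trichome genes numbered 6, 3 and 4, and without SiCD_A pool 2, higher cytokinin genes 7 and lower trichome genes 3. The camera direction and the median differed in sign for jasmonate and ethylene (median 0.01, camera down) and for trichome and epidermis (median -0.02, camera up).

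**Figure D2:**
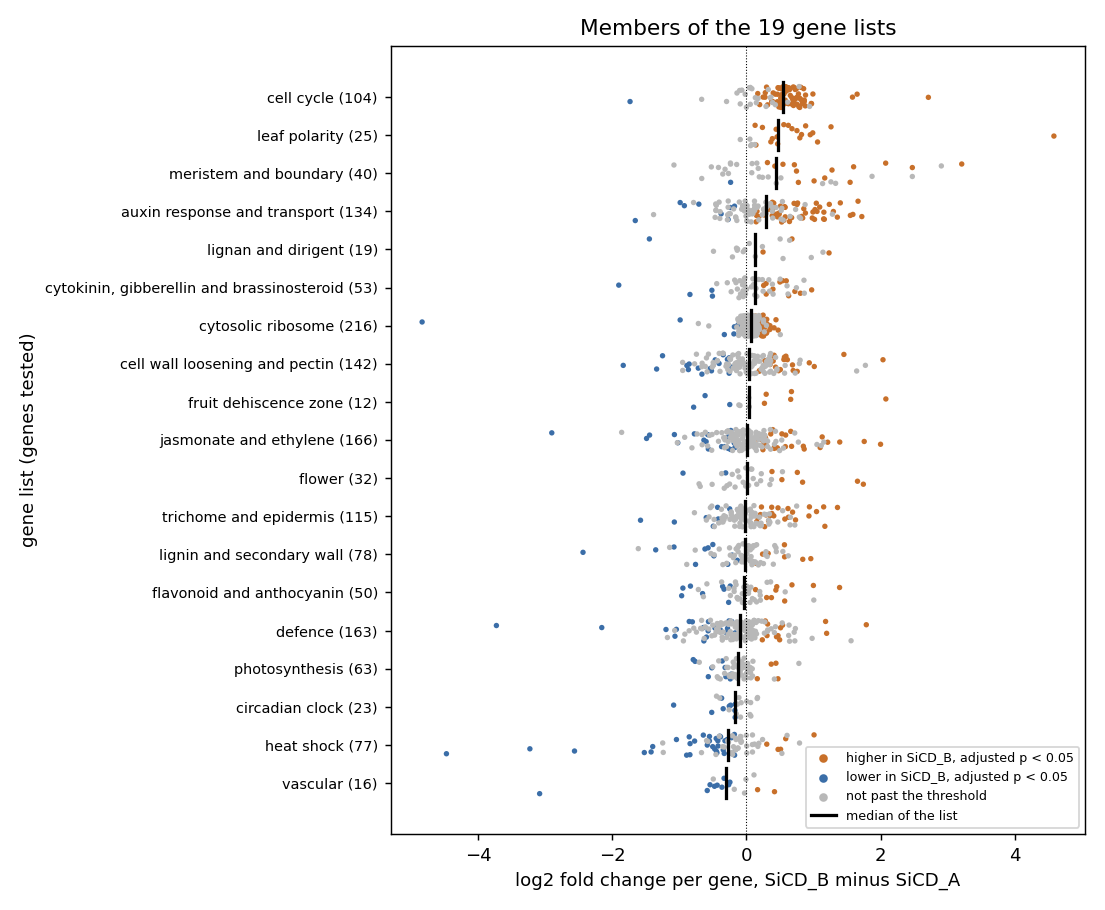
Log2 fold change, SiCD_B minus SiCD_A, of each tested gene of the 19 lists (points, coloured where adjusted p was under 0.05), with black lines for the list medians. The cell cycle median lies at 0.54, that of leaf polarity at 0.46 and that of vascular markers at -0.30.

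The last comparison asked whether called genes gather around the allele on linkage group 8. They did not over the linkage group as a whole. On linkage group 8, 587 of 2020 tested genes were called (29.1%), against 31.6% on the others. The 30 other tested genes nearest to KAN1, spanning 4138985 to 6045343, held 16 called genes, of which 4 changed at least 2-fold. The largest change was in LOC105167721 (4138985 to 4139083), an uncharacterized gene that fell from 81.3 ± 7.67 to 4.85 ± 0.784 CPM, a log2 fold change of -4.07 (SE 0.12, adjusted p = 8.70e-06). The others included TM9SF2 (5514150 to 5514286) and the potassium channel gene SKOR (LOC105167785, 4590903 to 4591120), which fell from 14.5 ± 2.62 to 2.52 ± 0.140 CPM. LOC105167721 and SKOR were named after their values were seen. LOC105167770 has no position in the deposited table and is not among the 30, so its rise is not in these numbers. By the RefSeq order it lies next to LOC105167769, which is among the 30 and starts 0.163 Mb from KAN1.

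The odds ratio of a call on linkage group 8 was 0.888 (95% confidence interval 0.801 to 0.984, two-sided Fisher's exact p = 0.0224, adjusted over 16 linkage groups 0.120). Only linkage group 10 passed that adjustment, with fewer calls (odds ratio 0.825, adjusted p = 0.0462), and for genes changed at least 2-fold its ratio turned to 1.20 (Fisher's exact p = 0.257). That on linkage group 8 turned to 1.12 at 2-fold (Fisher's exact p = 0.398), and without each pool in turn the ratio of all calls there was 0.904 to 0.954 with no p under 0.05. Of 241 windows of 1 Mb, 0 passed and 16 had an unadjusted p under 0.05. Of 125 windows of 2 Mb, 0 passed and 13 had an unadjusted p under 0.05. These include 2 neighbours on linkage group 8 that went opposite ways, 2 to 4 Mb with 42 of 193 genes called (21.8%, Fisher's exact p = 0.00379, adjusted 0.203) and 4 to 6 Mb, which holds KAN1, with 16 of 30 called (53.3%, p = 0.0161, adjusted 0.432). With DESeq2's test, with a CPM of at least 1 or without SiCD_B pool 1, 1 window passed, at 5 to 6 Mb on linkage group 10, with fewer calls than elsewhere. All these Fisher's tests take genes as independent, which genes of the same pools are not.

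**Figure D3:**
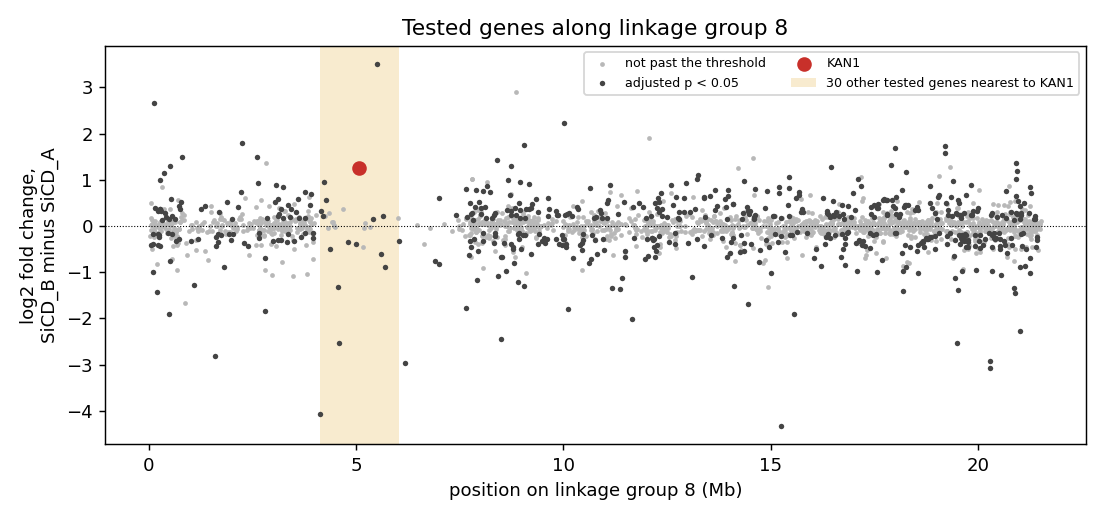
Log2 fold change, SiCD_B minus SiCD_A, of the tested genes along linkage group 8, against the position of the coding segment in Mb. Dark points had an adjusted p under 0.05, the red point is KAN1 at 1.26, and the shaded span holds the 30 other tested genes nearest to it.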

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

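The alternatives in scaling, filter and test, and the windows of 2 Mb, were planned before the data were examined. The upper-quartile scaling of the lists and every alternative for the added lists were chosen afterwards. KAN1 was called under every alternative run on it, at log2 fold changes of 1.19 to 1.33. Of 100 other named genes, 93 kept their side of the threshold in each alternative that gave a value, and 0 changed direction. With a limit of 2-fold the calls were 616, of which 264 were higher and 352 lower, which the stricter limit itself explains. Leaving out each pool gave 3919 to 5998 calls (2132 to 3118 higher, 1787 to 2895 lower) and 7 to 9 lists, with fewer samples in each fit. Camera with an estimated correlation, and the fewer degrees of freedom that come with it, gave 0 lists.

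The odds ratio on linkage group 8 was 0.904 to 0.954 without each pool, and 1.12 for genes changed at least 2-fold, where the direction turned and the cause was not tested. Windows of 1 Mb that passed numbered 1 with a CPM of at least 1 in 3 pools, 1 with DESeq2's test, and 0 to 1 without each pool, where the cause was not tested.

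Pool numbers were not taken to pair the samples. Deviations of same-numbered pools correlated across 21009 genes at 0.0701, 0.00909 and 0.0565, and at 0.176, 0.112 and 0.269 across the 16295 genes with a mean log2 CPM over 2. Each pool correlated best with its own number in both sets, a hint from the data and not from the design. With the replicate block the calls were 7181, lower photosynthesis genes numbered 19 and lower trichome genes 11, and the odds ratio on linkage group 8 was 0.906 (Fisher's exact p = 0.0512), where the cause was not tested. Sulfate transporter 1.3 (adjusted p = 0.160) and geraniol synthase (0.0940) were not called with the block. At 56123250 counts or more per pool, depth limits mainly genes near 0.1 CPM, such as KAN1-like in SiCD_A.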

Other observations

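Several further gene groups were chosen after the data had been seen, and 0 of the 9 passed camera with an estimated correlation. Growth-regulating factors and AINTEGUMENTA-like genes, which sustain cell division in young organs, were higher in SiCD_B for 18 of 18 tested members, with a median log2 fold change of 0.81. Zinc-finger homeodomain genes were higher for 8 and lower for 0 of 10 (median 0.55). Plastid ribosome genes were higher for 14 and lower for 1 of 43 (median 0.12), a number that fell to 4 without SiCD_B pool 2 or 3, 6 without SiCD_B pool 1, and 8 without SiCD_A pool 1 or 2, and was 26 with library size alone and 22 with the replicate block. Camera at the preset correlation gave adjusted p = 1.59e-11, 3.57e-05 and 0.000609 over the 9 added lists, and with an estimated correlation the adjusted p was 0.143, 0.143 and 0.507.

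Starch breakdown genes were lower for 14 and higher for 2 of 25 (median -0.56), among them alpha-glucan water dikinase (LOC105168286), which phosphorylates starch for its degradation, at -1.13 (SE 0.08). Senescence genes were lower for 7 and higher for 0 of 12 (median -0.30), and CYP72A219 cytochromes for 7 and 0 of 9 (median -2.46). The adjusted p at the preset correlation was 1.54e-05, 0.00360 and 3.57e-05, and with an estimated correlation 0.143 for each. Ribosome biogenesis genes were lower for 10 and higher for 1 of 47 (median -0.07, adjusted p = 0.00823, or 0.507 with an estimated correlation). The lower ones numbered 6 without SiCD_A pool 2, 5 without SiCD_B pool 3, and 4 with library size alone, where the list was not called (0.0599). Raffinose family genes were lower for 5 and higher for 3 of 20 (adjusted p = 0.108). Without SiCD_B pool 1 they passed (0.0475, 6 lower and 1 higher), and 1 was higher without SiCD_A pool 3 or SiCD_B pool 2. Glutathione transferases were lower for 5 and higher for 3 of 34 (0.701), and without each pool in turn 3 to 5 were lower and 0 to 3 higher. The dikinase lies outside the rule for named genes.

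The tests of read sharing, of the neighbourhood of KAN1 and of harvest time were chosen after the results they bear on had been seen. In the tissue test, the measure of spread and the bound were revised more than once after the median was known. The form written before used the spread over genes, and the one kept uses 2 SE over pools. The latter puts the value below the bound, while a 95% t interval does not. The 6 pools can be split into 3 and 3 in 10 ways, too few for a share under 0.05. In 1 of the 10, the real split, edgeR called 6433 genes, and the highest of the others was 0, with at most 1104 genes at an unadjusted p under 0.05. The real split gave 9 lists by camera and the highest of the others 8, also 1 of 10. The other splits keep part of the difference between groups, and the rest adds to their spread, so they do not stand for no difference. The odds ratio on linkage group 8 could be had in the real split alone (1 of 10), since the other splits called no gene.

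The rise of KAN1-like in SiCD_B has a technical reading, since it may share sequence with KAN1. A constant share of KAN1 reads counted on KAN1-like is argued against by the ratio of their counts, which was at least 5.35-fold higher in SiCD_B for every pairing of pools. The SiCD-B copy of KAN1 could still differ in sequence so that its reads land on KAN1-like, whose counts were 4.26% of those of KAN1 in SiCD_B and 0.421% in SiCD_A. Counts per gene hold no sequence, so this reading and a true rise of KAN1-like cannot be told apart.

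Large changes near KAN1 may reflect the parental haplotype fixed together with the allele rather than KAN1 itself. Of 631 runs of 30 neighbouring genes elsewhere, 12 (1.90%) held at least the 4 called genes changed 2-fold or more that were counted in the 30 genes nearest to KAN1, KAN1 left out, and the median run held 1. That number includes the genes that prompted the test. Counting only genes changed 2- to 8-fold, the 30 held 2, and 124 of the 631 runs (19.7%) held as many. Counting all calls of any size, the 30 held 16 against a median of 9 in the other runs, and 12 of the 631 runs held as many. This last count again includes the genes that prompted the test. In each count the runs match in number of genes, and not in length or gene density. The windows of linkage group 8 at 4 to 5 and 5 to 6 Mb held 20 and 10 tested genes, against 114 at 3 to 4 Mb. A linked haplotype and an effect of kan1 on its neighbours cannot be told apart from counts that hold no sequence. For the 3 genes changed at least 8-fold that the deposited table puts on unplaced scaffolds, the other tested genes of these scaffolds were called in 2 of 2 cases (100%). With 2 genes, scaffolds inherited together with linkage group 8 and other causes cannot be told apart.

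The rise of cell division and leaf polarity genes might come from a larger share of young dividing tissue in the SiCD_B pools. It needed ribosome biogenesis genes to rise by more than 0.1 and the median of senescence genes to lie below 0. The bound against it was a ribosome biogenesis median at or below 0. The senescence part was met (median -0.30). The ribosome biogenesis median was -0.0688, and the difference of its pool medians plus and minus 2 SE spanned -0.14 to -0.01. The rise of 0.1 was thus not seen in ribosome biogenesis genes. Both lists were chosen after the data had been seen, and the spread after the ribosome biogenesis median was known, so the test does not decide the question. The margin below 0 is narrow, since the 95% t interval of -0.17 to 0.02 reaches above 0, though not to 0.1. The ribosome biogenesis median was below 0 in every alternative run on that list, but only -0.02 with library size alone. Lower senescence genes (7 of 12) go with a larger share of young tissue, as do higher growth-regulating factors and AINTEGUMENTA-like genes (18 of 18). So do meristem and boundary genes (14 higher and 1 lower of 40), cytosolic ribosome genes (50 and 6 of 216) and plastid ribosome genes (14 and 1 of 43). Of these, the senescence, growth-regulating and plastid ribosome lists were chosen after the data had been seen, so their counts are no independent support. A larger share of such tissue in the SiCD_B pools therefore stays open. The shallow pool SiCD_A 3 is argued against, since the cell cycle median kept 94.7% of its value without it. A shift in harvest time, which would move dawn and evening clock genes apart at some hours and together at others, stays open, since LHY was lower and so was the median of the evening genes (-0.17), and the hour of harvest is not in the labels. The kan1 allele and chance differences at other loci between the 2 sets of 19 plants stay open, untested.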
